A study of Homo sapiens with 12 samples.

How the data were processed

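Poly(A)-selected RNA of 2 oral squamous cell carcinoma lines, CAL-27 and SCC-15, was sequenced in 12 libraries that fall into 4 groups of 3: shControl and shTTK of each line. Per the labels' protocols, the libraries were strand-specific (dUTP) and were read as paired ends of 150 bases on an Illumina NovaSeq instrument. The labels place all libraries in batch 1 and call the control samples both shControl and wild type without treatment, so whether a control hairpin was present is not settled by them. Whether the numbered replicates were separate cultures is not stated either, and p-values then measure only the spread between these samples, which may be technical.

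The deposited table holds raw counts per gene symbol, with no normalization, for 12 libraries. Per the submitters' processing notes, Trim Galore 0.6.6, STAR 2.7.7a and featureCounts 2.0.1 were used with the human build hg38. The annotation release, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Counts of genes that share sequence with a copy (AK4 and AK4P1, BOLA2B and BOLA2, MAGEA3 and MAGEA6, KRT6A and KRT14 and their paralogs, the IFITM genes) are therefore uncertain, and so are antisense genes such as FLG-AS1. The table has 58735 lines with 57167 distinct symbols. Of these lines, 1568 repeat a symbol of an earlier line, and 27 carry a spreadsheet date in place of a symbol (0.183% of all counts). All lines were kept as separate features. Coordinates are those of GENCODE release 29 on GRCh38, in which 58708 lines find their symbol. No table of the series had a column that could not be mapped to a sample (0 columns).

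Total counts ranged from 16176655 to 18484112 per library. Genes were kept with edgeR's filterByExpr on the 4 groups, which left 16946 genes. Scaling was TMM, and edgeR 4.0.16 in R 4.3.3 (limma 3.58.1) fitted a quasi-likelihood model with robust dispersions to the 12 libraries with 4 group means. This left 8 residual degrees of freedom per gene. Each gene's spread was moderated toward the trend over all genes, with a median of 64.9 prior degrees of freedom. The common biological coefficient of variation was 0.0393. The contrasts were shTTK against shControl in CAL-27, the same in SCC-15, the difference of the SCC-15 and CAL-27 changes, and the SCC-15 against the CAL-27 control libraries. P-values (two-sided) were adjusted by Benjamini-Hochberg within a contrast, and genes with an adjusted p under 0.05 were called. Standard errors are the log2 fold change divided by the root of the F statistic. Mean values are TMM-scaled CPM with the SD over 3 libraries.

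The design, the alternatives, 26 gene lists and the rule for named genes were fixed before the data were examined. The rule took TTK, the 8 genes per direction and line with the largest change (adjusted p under 0.05, at least 5 CPM in the higher group, no overlap between groups, no clone name), up to 3 members of each list by adjusted p, the 6 genes per direction with the largest smaller change among those called in both lines, and the 5 genes per direction with the largest value in the remaining contrasts. Some genes that the rule takes are not reported here. Of 1184 list entries, in which a gene counts once for each of its lists, 1183 were matched, 60 by an older symbol. The tested entries held 987 different genes, of which 80 belong to more than 1 list. The mTORC1-responsive list shares 22 members with the ATF4 list, 16 with the glycolysis list and 10 with the cholesterol list. Lists were tested with camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 26 lists of a contrast, and again with an estimated correlation. Members were counted as called over all tested genes and adjusted over the list alone. A fold against a group at 0 counts was set against a floor of 3 counts over the group and covers counting error only.

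Calls were recomputed with RLE size factors, DESeq2 1.42.0 (lists not recomputed), limma-voom, every gene with a read, a filter of 1 CPM in 3 libraries, each line alone, the replicate number as a block, and without each library in turn. After seeing the data, genes with a mean of at least 10 counts, the fit without the SCC-15 libraries numbered 1, and the fit without chromosome 4 genes were added. Replicate pairs were compared by a chi-square of their counts over genes with at least 20 counts per pair. Medians of log2 fold changes over 25 consecutive protein-coding genes (mean of at least 50 counts in the line) were set against 1000 permuted gene orders.

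The steps were tested on simulated data with 200 changed genes in each line and 200 between the controls. The difference between lines was scored on the genes changed in only 1 of the lines. In simulated CAL-27 data (16683 genes in the fit), 54.5% of genes with a log2 change of 0.5 and 78.8% with a change of 1 were recovered, and 5.74% of calls were unchanged genes. In simulated SCC-15 data (16683 genes), the shares were 60.6% and 84.8%, with 6.52% unchanged. For the difference between lines (16683 genes), 46.9% and 69.2% were recovered with 5.5% unchanged, and for the control comparison (16362 genes) 69.7% and 83.3% with 5.67% unchanged. A list shifted by 0.3 was estimated at 0.30. The data gave 4618 calls in CAL-27 and 4694 in SCC-15, far more than the changed genes simulated, so these shares need not hold for the data. Genes were simulated independently, so the error of the list test with correlated genes was not covered.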

Results

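Gene expression was measured by RNA sequencing in CAL-27 and SCC-15, both lines of human oral squamous cell carcinoma, with and without knockdown of TTK, the kinase of the mitotic spindle checkpoint also known as MPS1. The series title names mTORC1 and NF-kB as pathways of interest. Each of the 4 groups held 3 libraries. Total counts per library lay between 16176655 and 18484112, and 16946 genes were tested. The first principal component, with 88.3% of the variance, separated the lines. In SCC-15, the libraries numbered 1 stood apart from the others of their group in the mean chi-square per gene. It was 5.62 and 5.96 for control library 1 against libraries 2 and 3, which differed from each other by 1.98, and it was 3.07 and 3.78 for shTTK library 1, with 1.95 between libraries 2 and 3. The median chi-square, as a ratio to counting error alone, set control library 1 less apart (1.92 and 2.11, with 1.76 between libraries 2 and 3). This ratio was 2.19 and 2.63 for shTTK library 1, with 1.77 between libraries 2 and 3, and 1.93 to 2.14 for the CAL-27 pairs.

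TTK (chromosome 6, 80003887 to 80042527, plus strand, GRCh38) was lower in every shTTK library than in every control library of its line. In CAL-27 it fell from 49.4 ± 3.58 to 33.9 ± 1.57 CPM (SD, n = 3), a log2 fold change of -0.54 ± 0.066 (SE) that left 68.6% of the control level (edgeR adjusted p = 4.04e-10). In SCC-15 it fell from 69.9 ± 2.77 to 30.1 ± 3.80 CPM (SD, n = 3), a log2 fold change of -1.21 ± 0.065 that left 43.1% (edgeR adjusted p = 1.92e-25). The SCC-15 change minus the CAL-27 change was -0.67 ± 0.093 (edgeR adjusted p = 2.37e-08).

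**Figure D1:**
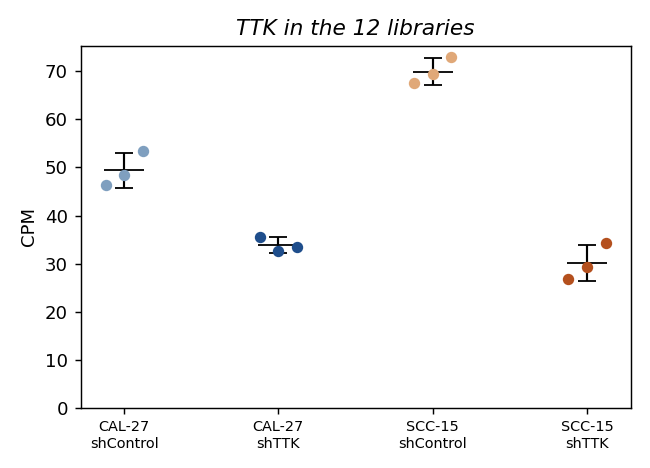
TTK in CPM (y axis, TMM-scaled) in each of the 12 libraries (points), with the mean and SD of 3 libraries per group (black lines). The shTTK libraries of CAL-27 had a mean of 33.9 CPM against 49.4 in the controls, and those of SCC-15 a mean of 30.1 against 69.9.

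In CAL-27 with TTK knockdown, genes of basal and differentiating keratinocytes rose, and genes of cholesterol synthesis and the cytokine genes CSF2 and IL6 fell. KRT14, a keratin of basal keratinocytes, rose from 3.44 ± 0.799 to 73.2 ± 2.96 CPM (SD, n = 3), a log2 fold change of 4.40 ± 0.075. KRT5, its partner keratin, rose from 886 ± 31.9 to 1924 ± 29.3 CPM, a log2 fold change of 1.12 ± 0.027. CSF2, which encodes GM-CSF, fell from 48.6 ± 2.86 to 8.88 ± 2.16 CPM (log2 fold change -2.46 ± 0.10), and IL6 from 81.5 ± 7.43 to 25.5 ± 2.90 CPM (-1.68 ± 0.075). Of the 16946 genes, 1961 were called higher and 2657 lower, and 277 and 148 of these changed by at least 2-fold. The excess of lower calls depended on the fit. With CAL-27 fitted alone 2217 were higher and 2330 lower, and with no count filter 1997 and 2040, whereas DESeq2 kept it (1704 and 2310).

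The other genes with the largest increases in CAL-27 were MMP10, a stromelysin (log2 fold change 2.99), the chemokine receptor ACKR3 (2.89), the epidermal calcium-binding proteins S100A7A (2.44) and S100A7 (2.33), the keratins KRT6A (2.33) and KRT15 (1.98), and the neurotrophin receptor NGFR (2.22). The largest decreases beside CSF2 and IL6 were TRAV8-1, a T cell receptor segment (-1.85), the adhesion receptor ADGRF5 (-1.82), cyclin D2 (CCND2, -1.77), the growth factor TGFB2 (-1.62) and ZBED6CL (-1.59). The sulfotransferase CHST6 fell from 8.74 ± 0.802 to 3.10 ± 0.189 CPM. The largest edgeR adjusted p among the genes named so far for CAL-27 was 1.51e-09, for CHST6. S100A7A, TRAV8-1 and ADGRF5 had 0 counts in the SCC-15 libraries.

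Of 35 basal keratinocyte genes tested, 30 rose, 2 fell and 3 were not called in CAL-27, and adjusted over the list alone 30 rose and 2 fell (camera adjusted p = 1.91e-73, and adjusted p = 2.64e-05 with an estimated correlation). Of 44 squamous differentiation genes, 23 rose and 2 fell, and adjusted over the list alone 27 and 2 (camera adjusted p = 7.03e-16, and adjusted p = 1.78e-04 with an estimated correlation). Their median log2 fold change was 0.78, or 0.63 without 4 members at or under 3 counts in a group. S100A8, a subunit of calprotectin, rose by 1.94 on the log2 scale while the keratin KRT80 fell by 0.68. Of 39 epithelial junction genes, 10 rose and 19 fell, and adjusted over the list alone 11 and 20. That list was not called (camera adjusted p = 0.0602), but it was without control library 1 (0.0257) or 3 (0.0293), and without SCC-15 control library 1 (0.0440) or shTTK library 3 (0.0434). Its keratins of simple epithelia, KRT8 and KRT18, had log2 fold changes of -0.69 and -0.55, whereas DSP, the desmosomal desmoplakin, rose by 0.41.

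Interferon-stimulated genes rose in CAL-27, 32 of 55 with 3 lower, and adjusted over the list alone 32 and 4 (camera adjusted p = 5.67e-12, and adjusted p = 1.14e-03 with an estimated correlation). IFI27 rose by 1.80, IFI6 by 0.83 and SAMD9 by 0.61 on the log2 scale. Cholesterol synthesis genes fell, 23 of 25 with 0 higher, and the counts were 23 and 0 adjusted over the list alone (camera adjusted p = 2.03e-28, and adjusted p = 1.31e-04 with an estimated correlation). SQLE, the squalene epoxidase, fell from 133 ± 2.43 to 78.9 ± 5.29 CPM (SD, n = 3). FDFT1, the squalene synthase, fell by 0.56 on the log2 scale. Of 23 YAP and TEAD targets, 13 fell and 4 rose, and adjusted over the list alone 14 and 5 (camera adjusted p = 6.68e-04, and adjusted p = 0.0473 with an estimated correlation). The receptor kinase AXL fell by 1.23 and the ectonucleotidase NT5E by 1.13, whereas IGFBP3 rose by 0.87.

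The pathways of the title were lower in CAL-27 by camera with the preset correlation, and not with an estimated one. Of 91 mTORC1-responsive genes, 42 fell and 22 rose, and adjusted over the list alone 43 and 24, with a mean log2 fold change of -0.09 (camera adjusted p = 5.77e-04, and adjusted p = 0.0786 with an estimated correlation). AK4, a mitochondrial adenylate kinase, fell by 0.82 and VEGFA, an angiogenic growth factor, by 0.65, whereas the amino acid transporter SLC7A5 rose by 0.59. Of its members, 10 also belong to the cholesterol list. Of 67 NF-kB targets, 30 fell and 5 rose, and adjusted over the list alone 33 and 11, with a mean of -0.25 (camera adjusted p = 3.08e-06, and adjusted p = 0.164 with an estimated correlation). CSF2 and IL6 had the largest changes among its called members, while TNFAIP2 rose by 0.54. Of 45 mTOR pathway components, 11 fell and 4 rose, as they did adjusted over the list alone, and the list was not called (camera adjusted p = 0.429). RPTOR, the scaffold of mTORC1, fell by 0.35.

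Cell cycle genes fell by small amounts in CAL-27. Of 62 S phase genes, 28 fell and 0 rose (camera adjusted p = 2.89e-05, and adjusted p = 0.107 with an estimated correlation), among them the histone chaperone ASF1B (log2 fold change -0.62) and the ribonucleotide reductase subunit RRM2 (-0.35). Of 59 G2/M genes, 18 fell and 0 rose (camera adjusted p = 0.0132, and adjusted p = 0.326 with an estimated correlation), among them the transcription factor FOXM1 (-0.37). In CAL-27 fitted alone, the G2/M list was not called (adjusted p = 0.0697). Of 43 spindle checkpoint and kinetochore genes, 14 fell, TTK included, and 1 rose (camera adjusted p = 0.0105, and adjusted p = 0.107 with an estimated correlation), and BIRC5, survivin, was at -0.30. Adjusted over the list alone, 28, 18 and 14 genes of these lists fell, and 1, 0 and 1 rose.

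Ribosomal protein genes rose in CAL-27 in 22 of 78 and fell in 2 (camera adjusted p = 9.18e-03, and adjusted p = 0.546 with an estimated correlation), and oxidative phosphorylation genes rose in 22 of 59 and fell in 4 (1.42e-03, and adjusted p = 0.230 with an estimated correlation), with the same counts adjusted over the list alone. ATF4 and unfolded protein response genes rose in 22 of 49 and fell in 13, and adjusted over the list alone in 23 and 14 (4.40e-03, and adjusted p = 0.230 with an estimated correlation). MYC targets fell in 21 of 50 and rose in 2, and adjusted over the list alone in 23 and 3 (6.65e-03, and adjusted p = 0.326 with an estimated correlation). Their mean of -0.053 was -0.027 without control library 2, and -0.034 without SCC-15 control library 2 or 3 or shTTK library 1 or 2. Immediate early genes rose in 12 of 39 and fell in 6, and adjusted over the list alone in 14 and 7 (0.0307, and adjusted p = 0.554 with an estimated correlation), and the transcription factor KLF4 rose by 1.01 while the phosphatase DUSP4 fell by 1.22. That list's call was lost without control library 1 (0.116) or 3 (0.0868) or shTTK library 1 (0.122), and its mean of 0.097 was 0.044 without control library 1 and 0.19 without control library 2.

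Fibroblast markers rose in CAL-27 in 5 of 8 and fell in 0, with the same counts adjusted over the list alone (camera adjusted p = 0.0196, and adjusted p = 0.107 with an estimated correlation), among them FBLN1 (log2 fold change 0.39) and COL1A1 (0.36, at 34.3 CPM in shTTK). In CAL-27 fitted alone, they were not called (adjusted p = 0.0635). Leukocyte markers had 1 higher and 1 lower of 3 (camera adjusted p = 0.760), and endothelial markers 0 and 2 of 4, with 1 and 2 adjusted over the list alone (0.171). Mesenchymal genes were higher in 11 and lower in 15 of 45, and adjusted over the list alone in 14 and 15 (0.161), with fibronectin (FN1) at -0.83 and SPARC at -0.60. The counts were 9 and 11 of 40 for p53 targets (9 and 12 over the list alone, 0.922), 4 and 7 of 22 for MHC class I genes (6 and 7, 0.484), 16 and 10 of 47 for glycolysis and hypoxia genes (18 and 10, 0.422), 2 and 0 of 24 for histone genes (1 and 0, 0.231) and 2 and 1 of 15 for mitochondrially encoded genes (2 and 1, 0.524), and none of these lists was called. Camera with the preset correlation also called between 6 and 11 lists in the other splits of the 6 CAL-27 libraries. Those splits mix the groups unevenly and keep part of the real difference, so these counts are not a rate of false calls.

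**Figure D2:**
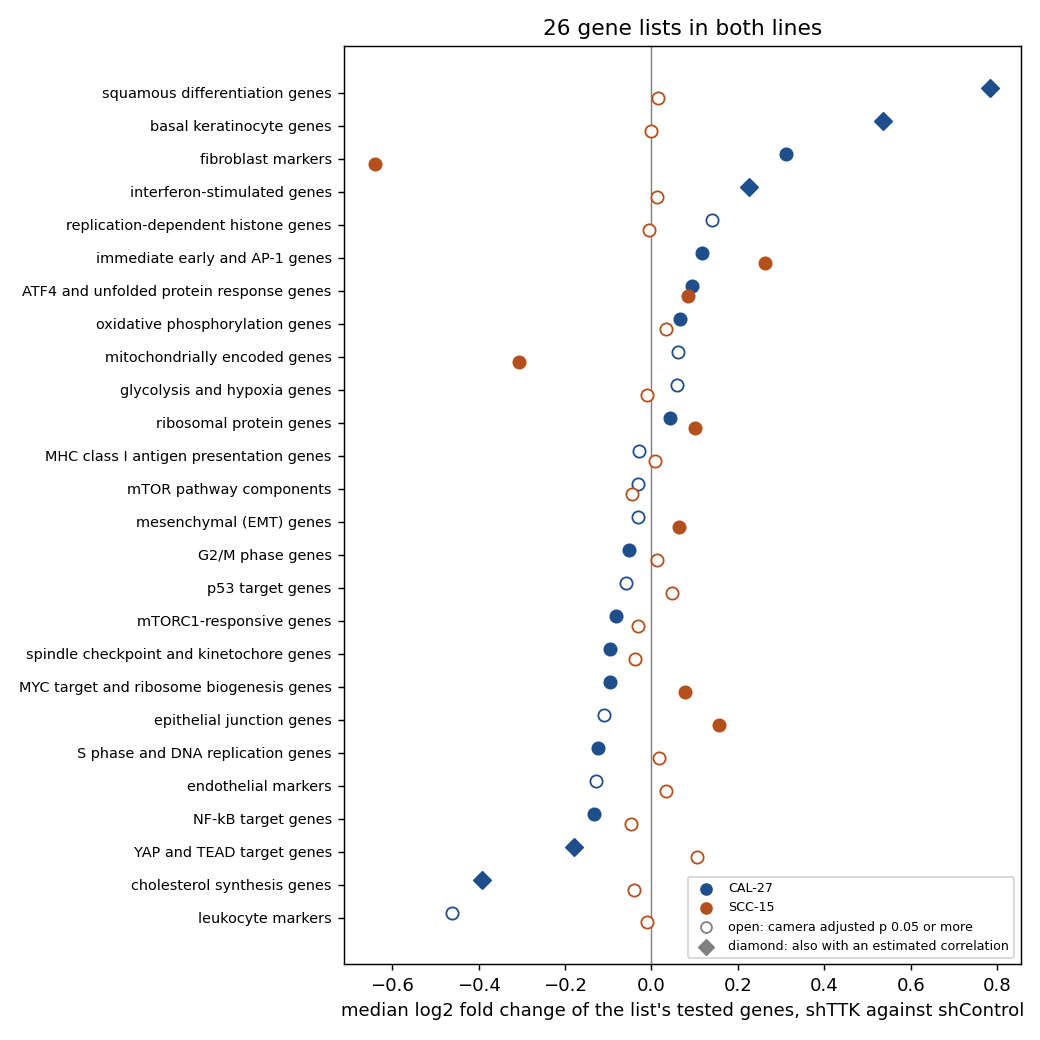
Median log2 fold change (x axis) of each list's tested genes (y axis) in CAL-27 (blue) and SCC-15 (orange). Filled symbols have a camera adjusted p under 0.05 and diamonds also with an estimated correlation, and basal keratinocyte genes had a median of 0.53 in CAL-27 and -5.45e-04 in SCC-15, and cholesterol synthesis genes -0.39 and -0.04.

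In SCC-15 with TTK knockdown, PDE2A, a cyclic nucleotide phosphodiesterase, fell from 172 ± 4.15 to 16.3 ± 0.548 CPM (SD, n = 3), a log2 fold change of -3.40 ± 0.064. SERPINB2, a plasminogen activator inhibitor, fell from 35.0 ± 3.20 to 7.82 ± 0.539 CPM (-2.16 ± 0.11). PTGS2, the inducible cyclooxygenase, rose from 51.5 ± 5.49 to 146 ± 2.04 CPM, and PXDN, a peroxidasin, from 18.6 ± 0.765 to 47.0 ± 2.12 CPM (1.33 ± 0.085). KRT14, which rose in CAL-27, fell from 763 ± 32.1 to 370 ± 10.9 CPM (-1.05 ± 0.035). Of the 16946 genes, 2277 were called higher and 2417 lower, and 119 and 279 of these changed by at least 2-fold. Without both libraries numbered 1, an alternative added after the data were seen, 1745 and 1912 were called.

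Further decreases in SCC-15 included SLFN11, a factor of the replication stress response (log2 fold change -3.36), EPDR1 (-2.79), FLG-AS1, antisense to filaggrin (-2.17), the arrestin ARRDC4 (-2.10) and the fatty acid binding protein FABP4 (-2.05). Further increases were the myopalladin gene MYPN (2.01), the inhibin subunit INHBB (1.79), the kallikrein KLK5 (1.47), SBK1 (1.36) and the phosphatase DUSP2 (1.23). The largest edgeR adjusted p among the genes named so far for SCC-15 was 1.55e-06, for DUSP2. BOLA2B had the largest fitted increase (3.03, edgeR adjusted p = 0.0495), but 282 of its counts lay in shTTK library 2, against 40 and 41 in the others. Without that library its log2 fold change was 1.45, and its call was lost with limma-voom (adjusted p = 0.191), without any one CAL-27 library (0.0532 to 0.0724) and without any one SCC-15 control library (0.114 to 0.135).

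NF-kB targets went both ways in SCC-15. Of 67, 18 fell and 11 rose, as they did adjusted over the list alone, and the list was not called (camera adjusted p = 0.156). Its mean was -0.41, or -0.25 in SCC-15 fitted alone, and its median -0.05, with 9 members at or under 3 counts in a group. SERPINB2, the adhesion molecule ICAM1 (-1.14) and complement C3 (-1.21) fell. Of 91 mTORC1-responsive genes, 33 fell and 26 rose, and adjusted over the list alone 34 and 30, and the list was not called (camera adjusted p = 0.234). AK4 fell by 1.32, HMGCS1, the cytosolic HMG-CoA synthase, fell by 0.78 and the autophagy receptor SQSTM1 fell by 0.40 on the log2 scale. Among 45 mTOR pathway components, 10 fell and 4 rose, as they did adjusted over the list alone (camera adjusted p = 0.0868), and the list was called without control library 1 (0.0461). RPTOR was at -0.57 and EIF4E, the cap-binding protein, at -0.69.

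Immediate early genes rose in SCC-15, 19 of 39 with 5 lower, and adjusted over the list alone 20 and 5 (camera adjusted p = 2.12e-05, and adjusted p = 0.496 with an estimated correlation). The AP-1 genes JUN and JUNB rose by 0.63 and 0.51, whereas KLF2 fell by 1.40. Epithelial junction genes rose in 15 of 39 and fell in 5, and adjusted over the list alone in 17 and 6 (1.08e-03, and adjusted p = 0.397 with an estimated correlation), with CDH1, E-cadherin, at 0.75, KRT8 at 0.48 and KRT18 at 0.36. Their mean of 0.075 was between 0.12 and 0.14 without CAL-27 control library 2, any one CAL-27 shTTK library, any one SCC-15 control library or SCC-15 shTTK library 2. Mesenchymal genes rose in 15 of 45 and fell in 7, and adjusted over the list alone in 17 and 10 (0.0246, and adjusted p = 0.468 with an estimated correlation), with FN1 at 1.10 and the adhesion molecule L1CAM at 0.63. Their call was lost without control library 3 (0.0521) or shTTK library 1 (0.0532), and the mean of 0.058 was 0.13 without control library 1, 0.098 without control library 2, 0.015 without control library 3 and 0.023 without shTTK library 2.

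Ribosomal protein genes rose in SCC-15 in 44 of 78 and fell in 7, and adjusted over the list alone in 47 and 8 (camera adjusted p = 1.22e-04, and adjusted p = 0.496 with an estimated correlation), RPLP2 by 0.37 with RPL23 at -0.39. ATF4 genes rose in 19 of 49 and fell in 10, and adjusted over the list alone in 22 and 11 (0.0256), and MYC targets rose in 17 of 50 and fell in 7, and adjusted over the list alone in 19 and 7 (0.0335), each with an adjusted p = 0.496 with an estimated correlation. The call of the MYC targets was lost without control library 1 (0.124) or shTTK library 3 (0.0580), and that of the ATF4 genes with limma-voom (0.0509). Fibroblast markers fell in 3 of 8 and rose in 1, as they did adjusted over the list alone (1.22e-04, and adjusted p = 0.0526 with an estimated correlation), with the complement proteases C1S at -1.97 and C1R at -1.32 and FBLN1 at 0.21. No list of SCC-15 was called with an estimated correlation.

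Mitochondrially encoded genes fell in SCC-15 in 7 of 15 and rose in 1, and adjusted over the list alone in 9 and 1 (camera adjusted p = 7.18e-04, and adjusted p = 0.496 with an estimated correlation). The cytochrome c oxidase subunits MT-CO2, MT-CO3 and MT-CO1 had log2 fold changes of -0.41, -0.31 and -0.25. All counts of these genes made up 3.25% ± 0.513 of the control libraries and 2.46% ± 0.195 of the shTTK libraries (SD, n = 3). Control library 1 lay above its group at 3.84%, and the mean log2 fold change of the list, -0.37, was -0.23 without it. MT-RNR2, the large mitochondrial ribosomal RNA, chosen after its values were seen, stood at 6849 CPM in control library 1 and at 2084 and 2190 CPM in control libraries 2 and 3, against 1034 to 1315 CPM in the shTTK libraries.

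The remaining lists were not called in SCC-15. Basal keratinocyte genes were higher in 9 and lower in 13 of 35, as adjusted over the list alone (camera adjusted p = 0.297), with KRT5 at -0.27 and the receptor EGFR at -0.52. Squamous genes were higher in 13 and lower in 11 of 44, and adjusted over the list alone in 14 and 11 (0.358), with KRT80 at 0.54 and FLG, filaggrin, at -1.82. Their mean was -0.24, or -0.41 without shTTK library 2, -0.40 without shTTK library 3, 0.020 in SCC-15 fitted alone and 0.014 with no count filter, and their median was 0.02, and camera's direction was up. Interferon genes were higher in 16 and lower in 12 of 55, and adjusted over the list alone in 16 and 13 (0.236), with the antiviral membrane proteins IFITM1 at 0.71, IFITM2 at 1.11 and IFITM3 at 0.56, a mean of -8.02e-05 (-0.026 to 0.067 over the alternatives) and a median of 0.01. Cholesterol genes were higher in 4 and lower in 10 of 25, and adjusted over the list alone in 5 and 10 (0.134).

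Of the cell cycle lists in SCC-15, spindle genes were higher in 8 and lower in 11 of 43 (8 and 13 over the list alone, camera adjusted p = 0.308, SPDL1 at 0.54), G2/M genes in 12 and 9 of 59 (13 and 10, 0.453, KIF23 at -0.57) and S phase genes in 14 and 12 of 62 (15 and 12, 0.985, ASF1B at -0.80, mean -0.016, or -0.018 to 0.0089 over the alternatives, and median 0.018). The counts were 8 and 4 of 40 for p53 targets (8 and 4, 0.236), 4 and 7 of 22 for MHC class I genes (5 and 8, 0.788, mean -0.020, or -0.084 to -0.0030 over the alternatives, and median 8.46e-03), 12 and 10 of 47 for glycolysis genes (13 and 10, 0.746), 20 and 9 of 59 for oxidative phosphorylation (23 and 10, 0.236) and 8 and 4 of 23 for YAP and TEAD targets (8 and 4, 0.236). Histone genes were higher in 2 and lower in 1 of 24 (2 and 1, 0.792), with a mean of 0.19 and a median of -5.80e-03. That mean was 0.035 without shTTK library 1, 0.12 without control library 1 or shTTK library 2, and -0.043 in SCC-15 fitted alone. Among the 3 leukocyte (0.792) and 4 endothelial markers (0.867, with camera's direction down and a mean of 0.068), 0 were called in edgeR over all genes or over the list alone. The endothelial mean was between -0.57 and -0.081 without any one library.

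Changes in SCC-15 lay unevenly along the chromosomes, in bins and tests chosen after this was seen. Of 377 chromosome 4 genes with a mean of at least 50 counts, 212 fell and 13 rose, with a median log2 fold change of -0.24, and EIF4E is 1 of them, but the bins at 2.3 to 6.7 and 6.7 to 17.6 Mb had medians of 0.010 and 0.014. The median was 0.14 on chromosome 20, where 144 of 300 genes rose and 20 fell. More genes also fell than rose on chromosomes 7 (113 and 76), 9 (98 and 61), 11 (183 and 96), 12 (201 and 51), 15 (103 and 19) and 17 (243 and 84). On the remaining autosomes and the X chromosome more genes rose than fell, 218 and 40 on chromosome 19. The bin at 35.2 to 38.4 Mb of chromosome 17, where SLFN11 lies, had a median of -0.43. In CAL-27 the medians of chromosomes 4 and 20 were -0.04 and -0.02. The bin of 25 genes at 0.2 to 0.8 Mb of chromosome 11, where IFITM1, IFITM2 and IFITM3 lie, had a median of 0.20 in SCC-15, and the next bin, 0.8 to 3.1 Mb, with RPLP2, had 0.26. The median over all of chromosome 11 was -0.04 in SCC-15. Without chromosome 4 genes, an alternative added after the data were seen, 2247 genes were higher and 2169 lower.

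Changes shared by both lines included TIMP2, a metalloproteinase inhibitor, with log2 fold changes of -1.11 in CAL-27 and -1.34 in SCC-15, and AK4, with -0.82 and -1.32. The sodium pump subunit ATP1B1 had -0.81 and -0.83, filamin C (FLNC) -1.03 and -0.84, the collagen processing enhancer PCOLCE2 -0.73 and -0.74, and AK4P1, a pseudogene of AK4, -0.94 and -0.93. Among the genes that rose in both lines, KLK5 had 1.28 and 1.47, the collagenase MMP13 1.05 and 0.97, the NKG2D ligand ULBP1 0.79 and 0.87, the chloride channel ANO1 0.78 and 0.77, and AUTS2 0.74 and 0.79. Without both SCC-15 libraries numbered 1, ANO1 had 0.51 in SCC-15. The transcription factor EGR2 had 1.05 and 0.76, but its SCC-15 call (edgeR adjusted p = 0.0378) was lost with limma-voom (0.0619), without SCC-15 control library 2 (0.101) or 3 (0.118), without any one SCC-15 shTTK library (0.0729 to 0.0948) and without CAL-27 shTTK library 2 (0.0554) or 3 (0.0503).

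In all, 487 genes were higher in both lines, against 263 expected from independent lists (odds ratio 2.44, 95% interval 2.17 to 2.73, Fisher's exact p = 6.12e-48), and 679 were lower in both, against 379 (odds ratio 2.48, 2.24 to 2.74, Fisher's exact p = 2.87e-64). Genes that moved in opposite directions also exceeded independence. Of these, 324 rose in CAL-27 and fell in SCC-15, against 280 expected (Fisher's exact p = 0.00280), and 491 did the reverse, against 357 (Fisher's exact p = 1.35e-15). Fisher's test treats genes as independent, which they are not. Genes with few counts in a line can hardly be called there, which can raise the overlap in every direction. Of the 16946 genes, 13887 had a mean of at least 10 counts in both lines. Of the 1981 genes called in both lines, 58.9% (1166) had the same sign, with a Pearson's r of 0.0155 and a Spearman's rho of 0.179. Across the 16946 genes, which are not independent replicates, the log2 fold changes of both lines had a Pearson's r of 0.00520 and a Spearman's rho of 0.0602.

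**Figure D3:**
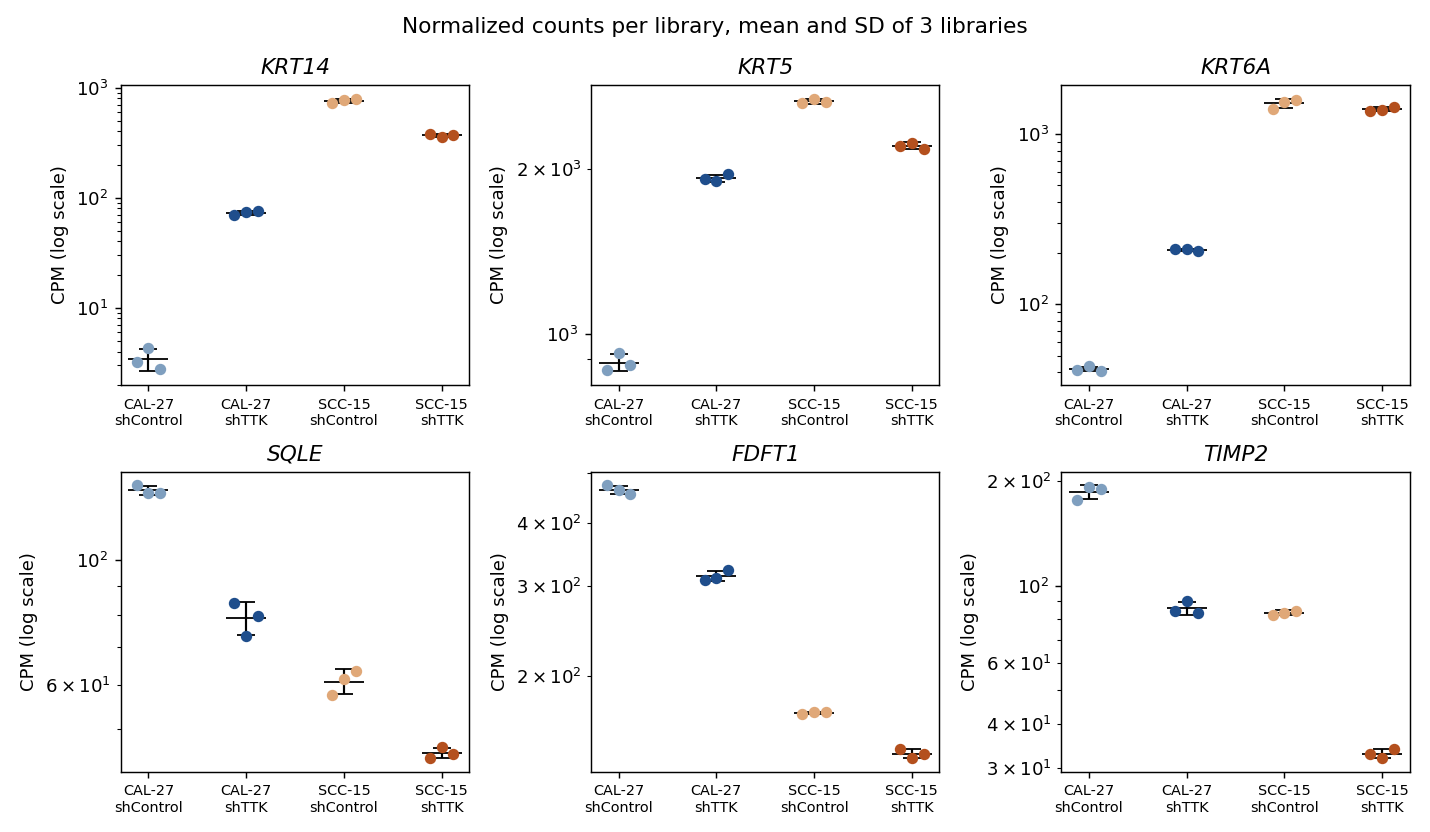
Level of 6 genes in each library in CPM (y axis, log scale, with its own range in each panel), with the mean and SD of 3 libraries per group. KRT14 rose from 3.44 to 73.2 CPM in CAL-27 and fell from 763 to 370 in SCC-15, and TIMP2 fell in both lines, to 86.0 and 32.9 CPM.

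The knockdown change differed between the lines for 4304 genes, higher in SCC-15 for 2250 and lower for 2054. TTK itself had a log2 fold change of -0.54 in CAL-27 and of -1.21 in SCC-15. A different response of the lines therefore cannot be told apart from the unequal depth of the knockdown or from other differences between the derivatives. KRT14 had the most negative difference among the named genes, -5.44 ± 0.083 (edgeR adjusted p = 1.21e-50), and MYPN differed by 3.29 ± 0.55 (edgeR adjusted p = 1.28e-06). Of the 10 genes that the rule named for this comparison, 8 had at most 30 counts in the 6 libraries of a line, so that their fitted values depend on the prior count. These were the endocytic protein EHD3 (6 counts in SCC-15), vimentin (VIM, 21 in CAL-27), the phosphodiesterase PDE3B (7 in CAL-27), TUSC1 (6 in CAL-27), the keratin pseudogene KRT16P6 (10 in CAL-27), the ammonium transporter RHCG (5 in SCC-15), S100A7 (2 in SCC-15) and EVA1C (8 in CAL-27). The calls of TUSC1, PDE3B, EHD3, RHCG and S100A7 were lost without at least 1 single library, with a highest edgeR adjusted p in these fits of 0.194 for TUSC1 without CAL-27 control library 2, 0.0702 for PDE3B without CAL-27 shTTK library 2, 0.0639 for EHD3 without SCC-15 shTTK library 2, 0.0749 for RHCG without SCC-15 control library 1 and 0.127 for S100A7 without SCC-15 control library 1.

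Basal keratinocyte genes differed between the lines by a mean of -0.81, 1 higher and 29 lower of 35, and 1 and 31 adjusted over the list alone (camera adjusted p = 1.10e-51, and adjusted p = 1.39e-04 with an estimated correlation). Cholesterol synthesis genes differed by 0.37, 17 and 1 of 25, and 20 and 1 adjusted over the list alone (2.27e-10, and adjusted p = 2.85e-03 with an estimated correlation), and fibroblast markers by -1.11, 0 and 6 of 8 on either count (1.32e-08, and adjusted p = 2.85e-03 with an estimated correlation). The mTORC1-responsive genes (32 and 24 of 91, and 39 and 25 over the list alone, camera adjusted p = 0.225) and NF-kB targets (17 and 14 of 67, and 19 and 17 over the list alone, 0.784) were not called for a difference. The NF-kB mean was -0.16 and the median 0.05, with a mean of -0.070 without SCC-15 control library 3, -0.033 with no count filter and -0.025 with limma-voom. The histone genes had a mean of 0.05, which ranged from -0.19 to 0.11 over the alternatives and was -0.093 without SCC-15 shTTK library 1 and -0.011 without SCC-15 shTTK library 2, and a median of -0.23 (2 and 1 of 24, 0.666).

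The control libraries of the lines differed in 12875 genes, 6404 higher in SCC-15 and 6471 lower. The imprinted gene PEG10, the cancer testis antigen MAGEA1, the keratin KRT4 and the phosphate transporter SLC20A2 had 0 counts in CAL-27 controls and were at least 1405-fold, 1177-fold, 849-fold and 633-fold higher in SCC-15 controls. MAGEA3, MAGEA6 and TMEM30B had 0 counts in SCC-15 controls and were at least 2115-fold, 1984-fold and 1834-fold higher in CAL-27 controls. The chemokine CCL2 stood at 1501 ± 83.4 CPM and SPARC at 547 ± 8.08 CPM in CAL-27 controls (SD, n = 3), against 6 and 2 counts in the SCC-15 controls, a ratio of 14220 for SPARC (3936 to 117426 by counting error). TTK was higher in SCC-15 controls by 0.50 ± 0.061 on the log2 scale (edgeR adjusted p = 2.59e-11).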

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

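The difference between the lines was a planned comparison, tested for each gene as an interaction term and for each list with camera on that term. Values are the SCC-15 change minus the CAL-27 change on the log2 scale. SPRY4 and DUSP4 were chosen after their values were seen, and so were all tests of the keratinocyte pattern except that of the summed keratin counts, and the fit without both SCC-15 libraries numbered 1.

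The knockdown change was higher in SCC-15 than in CAL-27 for 2250 genes and lower for 2054. TTK itself differed by -0.67, so the line cannot be told apart from the depth of the knockdown in these differences. Among keratinocyte genes, KRT14 differed by -5.44, the basal keratinocyte list by a mean of -0.81 and the squamous differentiation list by -1.20 (camera adjusted p = 0.0113, and adjusted p = 0.0657 with an estimated correlation). MYPN differed by 3.29, and SPRY4 and DUSP4 by 1.91 and 1.90. Vimentin (VIM) differed by 4.07, EHD3 by 4.33, PDE3B by 4.06, TUSC1 by 3.92, KRT16P6 by -5.23, RHCG by -5.05, S100A7 by -4.98 and EVA1C by -4.76. These last 8 genes had at most 30 counts in the 6 libraries of a line, so the sizes are fitted values that depend on the prior count and not measured folds, and with limma-voom those of EHD3, PDE3B, TUSC1, KRT16P6, RHCG and EVA1C were smaller by over 1.5 times (2.14, 2.19, 1.90, -2.77, -2.98 and -2.81). The call of TUSC1 was lost with DESeq2 (adjusted p = 0.0576), limma-voom (0.0716) and no count filter (0.0642), and without CAL-27 control library 2 (0.194) or any one CAL-27 shTTK library (0.0783 to 0.0820), over a range of 0.0225 to 0.194. That of PDE3B was lost with no count filter (0.0584) and without CAL-27 control library 2 (0.0570) or any one CAL-27 shTTK library (0.0654 to 0.0702), over a range of 0.0235 to 0.0702. That of EHD3 was lost with limma-voom (0.0543) and without SCC-15 shTTK library 2 (0.0639) or 3 (0.0575), over a range of 0.00410 to 0.0639. That of S100A7 was lost with no count filter (0.0623), without SCC-15 control library 1 (0.127) or 3 (0.127) and without any one SCC-15 shTTK library (0.0592 to 0.0625), and that of RHCG without SCC-15 control library 1 (0.0749). Without both SCC-15 libraries numbered 1 these reached the highest of their values, 0.173 for S100A7 (lowest 0.00117) and 0.122 for RHCG (lowest 0.00224).

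Among the other lists, cholesterol synthesis genes differed by 0.37 and fibroblast markers by -1.11, and both calls held with an estimated correlation. The cholesterol difference was 0.24 with no count filter. The YAP and TEAD targets differed by 0.39 (camera adjusted p = 1.84e-03, and adjusted p = 0.0657 with an estimated correlation), or by 0.25 without CAL-27 shTTK library 2 or SCC-15 shTTK library 1 or 2. Interferon-stimulated genes differed by -0.27 (1.36e-03, and adjusted p = 0.0657 with an estimated correlation). Epithelial junction genes differed by 0.14 (1.16e-04, and adjusted p = 0.0657 with an estimated correlation), or by 0.22 without SCC-15 control library 1. MYC targets differed by 0.12 (8.80e-05) and S phase genes by 0.11 (1.16e-03), each with an adjusted p = 0.228 with an estimated correlation. G2/M genes differed by 0.082 (0.0103, and adjusted p = 0.456 with an estimated correlation) and mitochondrially encoded genes by -0.46 (1.84e-03, and adjusted p = 0.539 with an estimated correlation).

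The number of genes with a difference, 4304, was reached by 2 of 100 drawn splits of both lines, the real one included. The highest other count was 4833, in the split that kept the CAL-27 groups and exchanged those of SCC-15, which tests the sum of the 2 changes. The count of genes called in the same direction in both lines, 1166, was reached by 1 of 100 splits, with 815 as the highest other. A line with mixed groups left at most 1 gene called, so the 98 splits that mixed a line had to fall short, and the splits decide nothing about either count. The number of lists called for a difference, 11, was reached by 10 of 100 splits, with a highest other count of 15. The 9 others that reached it kept the real groups of CAL-27 and so carry its change, and the 80 that mixed the groups of both lines reached at most 8 lists, so the splits do not decide about that number either. A split with mixed groups is uneven and keeps part of the real change, so its count of lists is not a rate of false calls. For 10 splits of 6 libraries the splits are too few for a share under 0.05. The real count and the highest other were 4618 and 1 genes in CAL-27, 4694 and 0 in SCC-15, 12875 and 0 between the controls, 16 and 11 lists in CAL-27, and 8 and 3 lists in SCC-15, each count being reached by 1 of the 10.

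Basal and squamous keratinocyte genes rose in CAL-27, and RNA or cells of SCC-15, in which KRT14 is abundant, are argued against, since 32 genes outside the lists, at or under the floor in CAL-27 controls and at 10 CPM or more in SCC-15 reached 0.153% of their SCC-15 level in CAL-27 shTTK, where KRT14 gained 9.14% of its own. Reads shared between keratin paralogs could explain part of the keratin changes: the summed CPM of 35 keratin genes and pseudogenes rose by 0.22 on the log2 scale, from 4441 ± 110 to 5183 ± 47.1 (SD, n = 3). That lies between the small change predicted if reads only moved between keratins and the larger one that a rise of all keratins predicts. Where a keratin truly rose and its reads were spread over its paralogs, the sum would rise as well. The sum also holds keratins that fell in CAL-27, among them KRT8, KRT18 and KRT80. A modest change of the sum can therefore come from opposite changes as well, so the sum cannot decide whether keratin reads were shared. This bears on the keratins alone, and of the 65 members of the lists that are not keratins, 43 rose and 3 fell. A difference between the CAL-27 derivatives other than TTK cannot be told apart from the knockdown either, and the effect of the knockdown itself stays open. The labels do not tell more than 1 shTTK derivative of the line apart. They do not say whether the shTTK samples come from a pool, a clone or several hairpins.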

How the results depend on the processing

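The fits with genes of at least 10 mean counts, without both SCC-15 libraries numbered 1 and without chromosome 4 genes were chosen after the data were seen. Among the named genes and the lists, no called result reversed under any alternative, and the other called genes were not followed for a reversal. Yet 14 list means that were not called changed sign under at least 1 alternative, among them the endothelial markers of CAL-27 (-0.33, and -0.33 to 0.63) and the squamous genes of SCC-15 (-0.24, and -0.41 to 0.020). Each count of called genes stayed within 1.5 times its value. Genes called higher and lower ranged from 1575 to 2275 and 1988 to 2833 in CAL-27, from 1745 to 2474 and 1912 to 2429 in SCC-15, from 1889 to 2369 and 1738 to 2089 for the difference between lines, and from 6062 to 6632 and 6042 to 7029 between the controls. Those higher and lower in both lines ranged from 385 to 553 and from 480 to 698. DESeq2 also called 3999 of the 4618 genes of CAL-27 and 4141 of the 4694 of SCC-15, and 2727 and 2946 were called whichever single library was left out. With the estimated correlation the mTORC1-responsive list (mean -0.091) and the NF-kB list (mean -0.25) of CAL-27 were no longer called, at an adjusted p of 0.0786 (2.00e-04 to 0.0786 over all alternatives) and 0.164 (9.13e-10 to 0.164). The means are those of the preset correlation by construction, and only the error of the test differs. Calls of the genes and lists named were counted once per result and fit. Of these, 46 were lost with 1 library left out, 27 with the estimated correlation, 7 with limma-voom, 7 with a line fitted alone, 6 without a count filter and 1 with DESeq2. In turn, 8 were gained with 1 library left out and 4 without a count filter. Of the alternatives added later, the fit without both libraries numbered 1 lost 6 calls and gained 3, and the fit without chromosome 4 genes lost 2. No call of these changed with RLE factors, the CPM filter or, for the results it covered, genes of at least 10 mean counts, and lists were not recomputed with DESeq2. Same-numbered libraries of control and shTTK did not deviate together over all tested genes (correlations of -0.020 to 0.034), and not every library correlated best with its own number. These correlations cannot exclude a replicate effect on some genes. In SCC-15, library 1 had the highest mitochondrial share of counts in the control group (3.84%) and in the shTTK group (2.68%). With the replicate number as a block, 4562 genes were called in CAL-27, 4636 in SCC-15, 4239 for the difference and 12811 between controls, and BOLA2B, EGR2, MT-RNR1 and the mesenchymal list of SCC-15 were no longer called. Depth limits the genes near the floor, among them 8 of the 10 named for the difference between lines.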

Other observations

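The genes of the first paragraph and all tests of the mitochondrial pattern were chosen after the result was seen, and of the tests of the chromosomal pattern, that of an effect common to both lines. The pattern and its bins, and the fit without both SCC-15 libraries numbered 1, were also chosen after the data were seen.

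Among the immediate early genes, SPRY4 and DUSP4, both feedback inhibitors of ERK signalling, went in opposite directions in the lines, while the list itself was not called for a difference with all libraries (camera adjusted p = 0.0939, and 0.00600 to 0.745 over the alternatives). It was called without CAL-27 control library 1 (0.00600) or shTTK library 1 (0.0262), without SCC-15 control library 1 (0.0288) or both SCC-15 libraries numbered 1 (0.0297), and with no count filter (0.0134). SPRY4 fell in CAL-27 from 10.2 ± 1.2 to 4.26 ± 1.12 CPM (SD, n = 3) and rose in SCC-15 from 2.04 ± 0.0908 to 3.21 ± 0.514 CPM, with log2 fold changes of -1.26 ± 0.17 and 0.65 ± 0.21 (SE, edgeR adjusted p = 2.03e-09 and 0.0146). DUSP4, a phosphatase of ERK, fell from 253 ± 17.2 to 109 ± 7.55 CPM in CAL-27 and rose from 19.3 ± 0.620 to 31.1 ± 1.82 CPM in SCC-15, with log2 fold changes of -1.22 ± 0.044 and 0.69 ± 0.070 (edgeR adjusted p = 8.81e-30 and 9.05e-12). The changes differed between the lines for both genes (edgeR adjusted p = 2.31e-08 and 3.22e-26). The SCC-15 call of SPRY4 was lost without SCC-15 control library 1 (0.0503) or shTTK library 2 (0.111), over a range of 0.0111 to 0.111.

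The changes of SCC-15 lay unevenly along the chromosomes: the SD of the medians over 422 bins of 25 genes was 0.105, against at most 0.0519 in 1000 permuted gene orders (permutation p = 0.001, the smallest they can give). The p was the same in CAL-27 (SD 0.0527, against at most 0.0486) and for library 1 against libraries 2 and 3 within SCC-15 shTTK (0.0494, against 0.0316) and SCC-15 controls (0.0285, against 0.0254), so this p does not separate the knockdown from differences between replicates. The sizes did differ, with a chromosome 4 median of -0.24 for SCC-15 shTTK against shControl. For library 1 against libraries 2 and 3 that median was -0.038 within SCC-15 shTTK and 0.015 within SCC-15 controls. Genes of chromosome 4 had an odds ratio of 5.98 (4.83 to 7.43) for a lower call in SCC-15 (Fisher's exact p = 1.91e-60). Chromosome 4 was picked from these same data and its genes are not independent, so that test adds no separate support. Bias by GC content or gene length is argued against as the whole cause, since the SD stayed at 0.101 after a spline on both was removed, and so are the libraries numbered 1, without which the chromosome 4 median was -0.21, and an effect common to both lines, since the bin medians of the lines had a Spearman's rho of -0.0041 over 403 bins. A copy number difference between the SCC-15 derivatives is a candidate explanation, as chromosome 4 genes had a median of -0.28, -0.24 and -0.23 at low, middle and high expression, but it would have to leave out 2.3 to 17.6 Mb, where 2 bins had medians of 0.010 and 0.014. It was tested on expression alone, and an effect of the knockdown particular to SCC-15 stays open.

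Mitochondrially encoded RNA was lower in SCC-15 shTTK, with MT-RNR2 at -1.70 (edgeR adjusted p = 0.0181) and MT-RNR1 at -0.95 (0.0250). The libraries numbered 1 are argued against as the whole cause, since 12 of 15 members were lower and 0 higher without both, with a mean of -0.33, and the lowest control share of counts, 2.92%, lay above the highest of shTTK, 2.68%. In all libraries the list had an adjusted p = 0.496 with an estimated correlation, without control library 1 its mean was -0.23 and MT-RNR2 was at -0.91, and the call of MT-RNR2 was lost with limma-voom (0.0567), in SCC-15 fitted alone (0.113) and without shTTK library 2 (0.0657) or 3 (0.0645), over a range of 2.43e-04 to 0.113. The call of MT-RNR1 was lost without control library 3 (0.0882) or shTTK library 2 (0.0885) or 3 (0.0811), with no count filter (0.0577) and with the replicate block (0.117), over a range of 0.00244 to 0.117. RNA quality was not tested, and an effect of the knockdown stays open.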
